A study of Mus musculus with 8 samples.

How the data were processed

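RNA of endothelial cells sorted from mouse colon as CD45-negative, CD11b-negative and CD31-positive was measured on 8 Affymetrix Mouse Gene 2.0 arrays, 4 from allogeneic and 4 from syngeneic recipients. Per the labels' protocols, colon was digested for 60 min at 37 °C with 1 mg/ml collagenase IV, RNA was isolated directly after sorting with the mirVana kit, and targets were made from 700 pg of total RNA with the WT Pico kit, which amplifies it. The series' design text counts 4 transplanted mice per group, and the labels call the samples biological replicates. Groups and replicate numbers were taken from the sample titles.

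The authors deposited log2 values per probe set, made with Affymetrix Expression Console 1.4.1 and RMA per the submitters' processing notes. RMA corrects the background, normalizes quantiles and summarizes the probes of a set on the log2 scale. The level of summary and the probe annotation the authors used are not given in the sources used here. Scanner files were not used here, so no detection call was at hand, and a low value is given as a low signal and not as absence. The values of 4 Y-linked genes in these female recipients, at most 3.18, are the only guide to background used here. The table held 41345 probe sets with 0 missing values. By the platform annotation, 23521 probe sets had exactly 1 gene symbol, 1814 had several and 16010 had none, and only the first kind was named. For the 1082 genes with more than 1 such probe set, that with the highest mean over the 8 arrays was used, which left 22180 genes. Probe sets of a called gene disagreed for some genes, for example Cyp2f2 (log2 changes of 1.01 and 0.09), Abat (1.29 and 0.51) and Mfsd4a (1.07 and 0.15).

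The main test was fixed before the data were examined. A linear model with 1 coefficient for the group was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with no filter on dim genes. Prior degrees of freedom were 4.65. Changes are allogeneic minus syngeneic, and p-values were adjusted by Benjamini-Hochberg over the 22180 genes with a threshold of 0.05. Lists for pathways and cell types, with 1106 distinct genes in all, were written down beforehand, and 996 of these genes were measured. Some genes are in several lists. The 39 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, and with fry. Each list's p-values were also adjusted over the list alone. Array means of marker lists were tested by two-sided exact permutation over the 70 labelled splits of the 8 arrays. The similarity of arrays was tested by one-sided exact permutation over the 35 distinct splits.

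Genes named in the text follow a rule. They are the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, without predicted genes and olfactory or vomeronasal receptors. Up to 4 members with the smallest p in each list, and Pecam1, Cdh5, Ptprc and Itgam, were added. Genes named for their level alone (Car1, Muc2, Krt8), for disagreeing probe sets and in the closing part were chosen after their values were seen.

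The pipeline was tested on simulated data, 5 sets of 22180 genes with 200 changed genes each, drawn among genes above the median probe set, and 4 arrays per group. Of genes changed 1.5-fold 20.8% were called, of 2-fold changes 65.6%, of 3-fold changes 90% and of 4-fold changes 95.6%. Of all simulated calls 5.42% were genes without a change. A list raised by 0.5 on the log2 scale was called in 5 of 5 sets and other lists, with hypoxia left aside, in 0 of 185 tests. The simulated genes varied independently, so this does not test lists whose members vary together.

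Alternatives covered the variance prior, filters on dim genes, scaling, array weights, the probe set rule, the replicate number as a block, thresholds, each array left out, and the settings of camera. The epithelial and the endothelial list means as covariates, the fit without syngeneic arrays 3 and 4, and the fit of all probe sets were added after the data were seen. No batch, slide or date was given with the values, so none was modelled.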

Results

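Gene expression was measured in endothelial cells of the mouse colon 2 days after bone marrow transplantation, early in graft-versus-host disease (GVHD), of which the colon is a target organ. All recipients were female C57BL/6 mice that received 5 days of busulfan and cyclophosphamide before transplantation of bone marrow and T cells. In the syngeneic group (n = 4) the donors were C57BL/6 mice, so that donor and recipient shared a genome. In the allogeneic group (n = 4) the donors were of the LP/J strain, whose T cells can attack the recipient's tissues. Cells that carried CD31 (the product of Pecam1) and lacked CD45 and CD11b were sorted from digested colon, and each of the 8 arrays held RNA of 1 sorted sample. Values are normalized log2 signals. They ran from 1.39 to 13.9, with a median per array between 4.68 and 4.79, and 22180 genes were tested. The number of arrays sets the precision of each comparison.

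The sort markers and other endothelial genes were well above the middle of the range. Pecam1 averaged 10.4 and Cdh5, which encodes the adherens junction protein VE-cadherin, 10.0 over the 8 arrays. The pan-leukocyte gene Ptprc (5.20) and Itgam (5.34), which encode the excluded markers CD45 and CD11b, lay near the median gene. Transcripts of colon epithelium were abundant on every array as well. Car1, a carbonic anhydrase of colonocytes, averaged 13.0 with a lowest value of 12.4, the goblet cell mucin Muc2 averaged 12.8 and the keratin Krt8 11.9. Genes of the Y chromosome stayed at or below 3.18 on all arrays.

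The first question was whether donor type separated the arrays over all genes. The mean correlation of gene values was 0.986 among allogeneic arrays, 0.979 among syngeneic arrays and 0.977 between the groups. Within-group correlations exceeded between-group correlations by 0.00542 on average, more than in any other of the 35 ways to split the arrays 4 and 4 (one-sided exact permutation p = 0.0286, the smallest possible with 4 against 4 arrays). The first principal component held 34.9% of the variance and the second 17.2%. On the first, the allogeneic arrays lay between -27.4 and -13.2 and the syngeneic arrays between -3.67 and 51.1. Syngeneic arrays 3 and 4 stood apart from the rest, with scores of 28.8 and 51.1. Their mean correlations with the other 7 arrays, over all probe sets, were 0.962 and 0.963. Their means over the pan-endothelial gene list were the highest, 8.79 and 9.66. Allogeneic arrays 1 and 2, with the lowest scores on the first component, had the lowest, 7.47 and 7.63. Scores on the first component differed between donor types (two-sided exact permutation p = 0.0286, the smallest possible). Whether that reflects donor type itself or endothelial content was not tested.

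**Figure D1:**
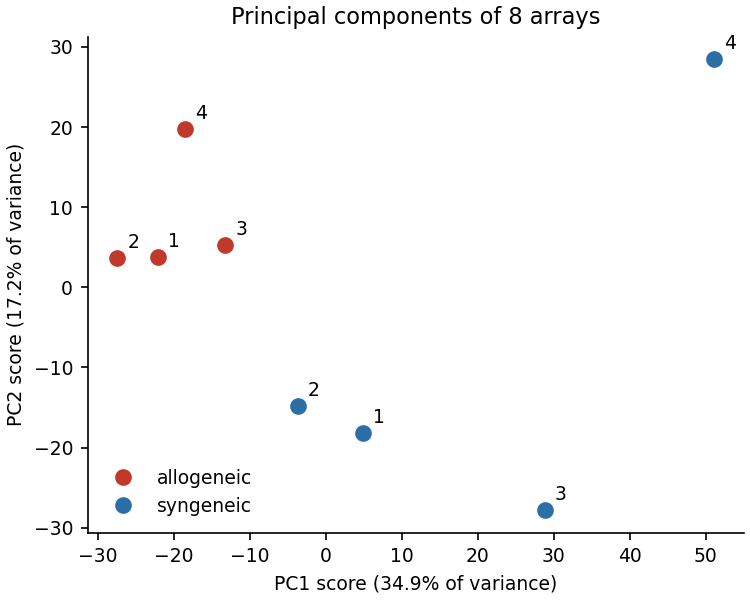
Principal components of the 8 arrays over all genes tested. The horizontal axis is the score on the first component (34.9% of the variance) and the vertical axis the score on the second (17.2%). Each point is 1 array, coloured by donor type and numbered by replicate. All 4 allogeneic arrays have first scores of -13.2 or less, and syngeneic arrays 3 and 4 lie farthest to the right.

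The main comparison asked which genes differed between the sorted colon samples of allogeneic and syngeneic recipients at day 2. Epithelial transcripts were abundant on every array, so a change cannot be assigned to endothelial cells. At an adjusted p below 0.05 in limma, 104 genes changed, 79 higher and 25 lower after allogeneic transplantation. At an unadjusted p below 0.05 there were 2937, of which 1733 were higher. In each of the 104 genes the 4 allogeneic arrays all lay on one side of the 4 syngeneic arrays, which selection by a small p makes likely. Such separation held for 8.55% of all genes, where chance gives 2.86% on average. Genes vary together, and the spread of that share by chance was not measured. The median log2 change was 1.18 among the higher genes and -1.16 among the lower ones, and 53 and 18 of them changed at least 2-fold.

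The 12 largest rises included those of several enzymes. The largest rise was that of the cytochrome P450 gene Cyp2c68, from 4.48 ± 0.54 in syngeneic to 8.45 ± 0.49 in allogeneic arrays (SD, n = 4 each), or 15.7-fold (log2 change 3.97 ± 0.30 SE, limma adjusted p = 0.000638). Its close relative Cyp2c69 rose 6.64-fold (2.73 ± 0.28 SE). Its syngeneic values (3.10 to 3.38) lay near the highest value of a Y-linked gene (3.18), so the size of this rise is uncertain. The sequences of this family are so alike that signal of 1 member can be read at the probes of another, and the values of both genes are uncertain in that respect. Nxpe2 had the smallest adjusted p (0.000446) and rose 6.10-fold, from 6.65 ± 0.32 to 9.25 ± 0.20. Hao2, a peroxisomal oxidase of 2-hydroxy acids, rose 5.82-fold and Otc, the ornithine transcarbamylase of the urea cycle, 5.38-fold. Tgm3, a protein-crosslinking transglutaminase, rose 5.44-fold. The sulfotransferase gene Sult1c2 (4.92-fold, limma adjusted p = 0.0493) and the esterase gene Aadac (4.67-fold) followed. Fam83b (3.97-fold), the zymogen granule gene Sycn (3.93-fold), Mep1a (3.51-fold), a subunit of the brush border protease meprin, and Plbd1 (3.19-fold) completed the 12 largest rises. Standard errors of the log2 changes of these 12 genes were between 0.18 and 0.42. Tgm3, Sult1c2, Aadac and Mep1a lost the call with the epithelial covariate, with the endothelial one and without syngeneic arrays 3 and 4. Each also lost it in 5 of the 8 fits that left out 1 array. Fam83b, Sycn and Plbd1 lost it in some of these settings. With the epithelial covariate the log2 change of Sult1c2 was 1.49 in place of 2.30.

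The largest measured fall was that of Zbtb16, which encodes the transcription factor PLZF, from 7.51 ± 0.52 to 5.55 ± 0.37 (SD, n = 4 each), a log2 change of -1.96 ± 0.27 (SE, limma adjusted p = 0.0195). S100a8, a subunit of the neutrophil protein calprotectin, changed by -1.94 ± 0.18 (limma adjusted p = 0.00424) and was low in both groups, at 3.07 and 5.01. Its allogeneic values (2.59 to 3.41) lay near those of Y-linked genes, so the size of this fall is a lower bound. Lrg1, a secreted glycoprotein of the acute phase that also acts on vessel growth, changed by -1.90 ± 0.20. Clca4b (-1.82), Cxcl5 (-1.80), a chemokine for neutrophils, and the mast cell protease gene Prss34 (-1.75) fell by similar amounts. Tac1, the precursor of substance P, changed by -1.43 ± 0.14 (limma adjusted p = 0.0044). Upp1 (-1.31), a uridine phosphorylase, and the protease inhibitor gene Slpi (-1.29) fell as well. Cxcl10 (-1.26), an interferon-induced chemokine for T cells, Sting1 (-1.22), the adaptor of cytosolic DNA sensing, and Stat2 (-1.18), a transducer of type I interferon signals, complete the 12 largest falls. Cxcl10, Sting1 and Stat2 each lost the call with the epithelial covariate (limma adjusted p = 0.165, 0.132 and 0.098), with the endothelial one (0.11, 0.0797 and 0.0847), without syngeneic arrays 3 and 4 (0.129, 0.0668 and 0.0809), and in 6, 5 and 6 of the 8 fits that left out 1 array. In the first 3 settings their log2 changes were -0.91, -0.94 and -0.99 for Cxcl10, -1.10, -1.17 and -1.22 for Sting1, and -0.86, -0.96 and -0.92 for Stat2. Cxcl5, Prss34 and Upp1 also lost the call in these settings, and in 2, 5 and 5 of the 8 fits that left out 1 array. Zbtb16, Clca4b and Slpi lost it in some of these settings.

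**Figure D2:**
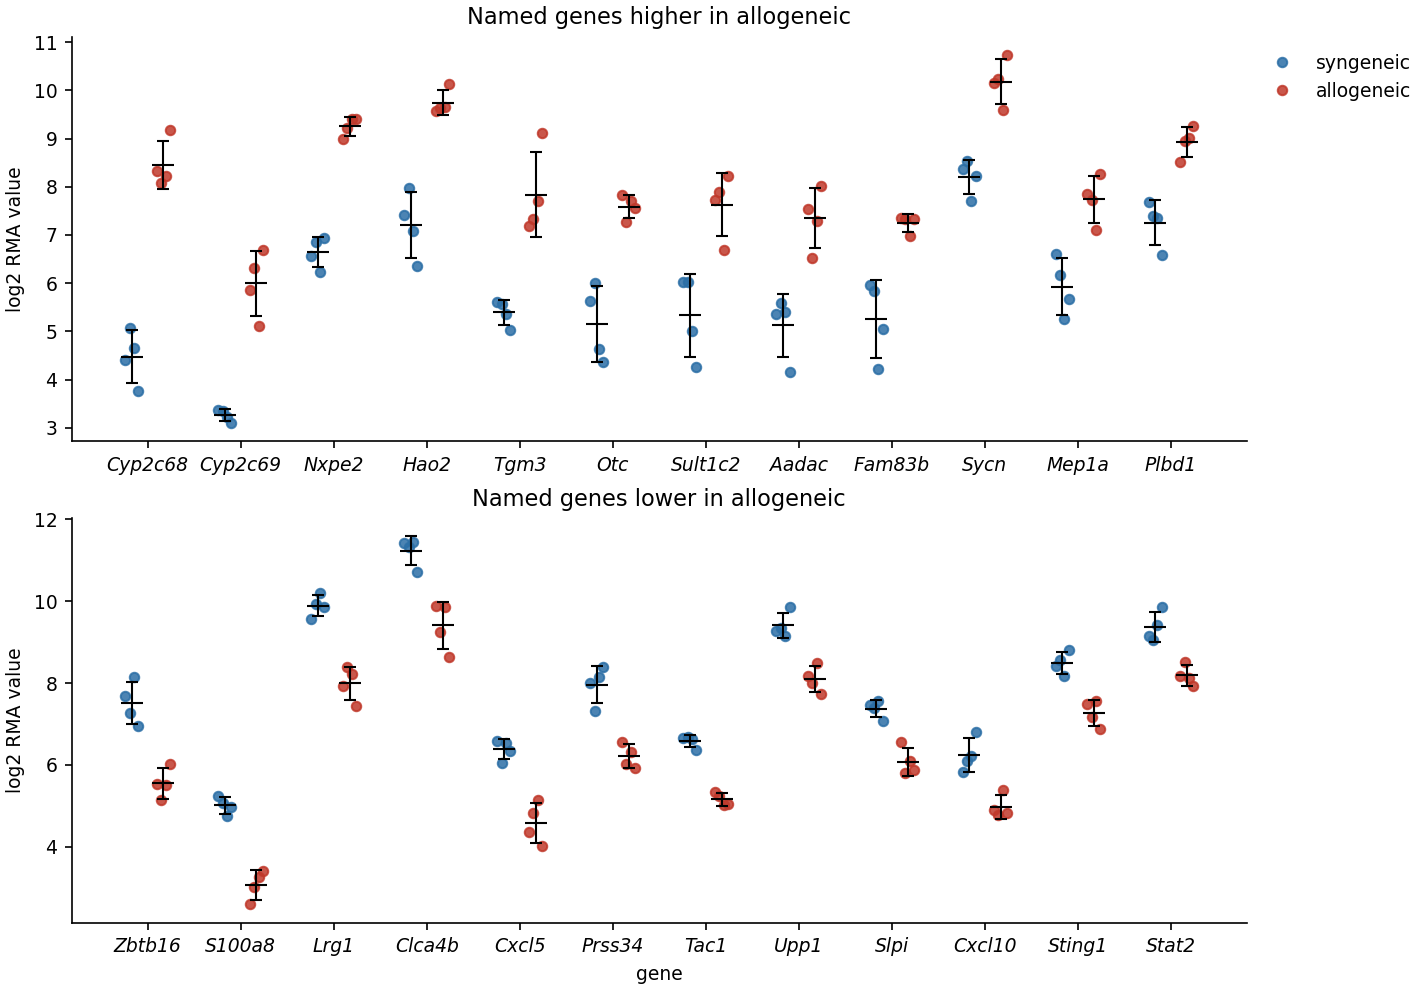
Normalized log2 values of the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom). Points are arrays (4 per group), horizontal lines are group means and bars are ± 1 SD. For every gene shown the groups do not overlap, as for Cyp2c68 at 4.48 against 8.45 and Tac1 at 6.59 against 5.16.

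The number of genes past the threshold depended on single arrays and on covariates for cell type signal. Leaving out 1 array gave between 4 higher genes (without allogeneic array 1 or syngeneic array 3) and 145 (without syngeneic array 2), and between 4 and 35 lower genes. With each array's mean over the colon epithelial list as a covariate, a setting chosen after the data were seen, 6 higher and 4 lower genes passed. With the endothelial list in that place, 19 and 10 did.

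The interferon lists had lower means in the allogeneic group. Of the 32 measured members of the interferon gamma response, 31 had a negative log2 change. Cxcl10 fell, the other 31 did not pass over all genes, and 22 members fell when p-values were adjusted over the list alone. Tap1, the peptide transporter of antigen presentation, had a log2 change of -1.10 (limma adjusted p = 0.0551). The guanylate-binding protein genes Gbp7 (-1.70, limma adjusted p = 0.0558) and Gbp10 (-1.72, limma adjusted p = 0.068) also just missed the threshold. The array means of the list were 7.26 ± 0.35 in allogeneic and 8.24 ± 0.40 in syngeneic samples (SD, n = 4 each), a 1.97-fold difference without overlap between the groups (two-sided exact permutation p = 0.0286). That p is the smallest possible with 4 against 4 arrays and was not adjusted over lists. Array means did not overlap in 11 of the 39 lists. Camera, which sets the list against all other genes, called it (adjusted p = 2.17e-21). Its mean log2 change was -0.98, and -0.62 with the epithelial covariate, -0.71 with the endothelial one and -0.80 without syngeneic arrays 3 and 4. The call was lost with the correlation among its genes estimated from the data (adjusted p = 0.237 with an estimated correlation). The pan-endothelial list also had a lower mean in the allogeneic group, 7.84 against 8.57.

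The type I interferon response gave a like picture. Of its 33 measured members Stat2 and Oasl1, an antiviral oligoadenylate synthetase-like gene (-1.03), fell, and 17 fell when adjusted over the list alone. Oas2 (-1.24) and Herc6 (-1.27) did not pass (limma adjusted p = 0.106 and 0.109). Its list mean was 6.83 ± 0.14 against 7.50 ± 0.43 (SD, n = 4 each) and passed camera (adjusted p = 7.05e-15). Syngeneic array 4 stood apart at 8.14 (others 7.23 to 7.37). The mean log2 change of -0.67 became -0.33 with the epithelial covariate, -0.37 with the endothelial one and -0.42 without syngeneic arrays 3 and 4, still past camera's threshold. The call was lost otherwise (adjusted p = 0.237 with an estimated correlation). None of the 21 measured genes of MHC class I presentation passed over all genes, while 10 fell and 1 rose when adjusted over the list alone. Among them were H2-Q4 (-0.89) and Tapbp (-0.70), which loads peptide onto class I molecules. This list passed camera (adjusted p = 2.32e-06, against an adjusted p = 0.338 with an estimated correlation), and its mean log2 change of -0.41 became -0.23, -0.29 and -0.33 in the same settings. MHC class II presentation did not pass (camera adjusted p = 0.302), with H2-Ab1 at -0.68 and Ctss at 0.74.

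Targets of the inflammatory transcription factor NF-kB and genes of leukocyte adhesion had lower means too. Of 29 NF-kB targets 27 had a negative log2 change. None passed over all genes and 17 fell when adjusted over the list alone, with Rel, an NF-kB subunit, at -0.70 (limma adjusted p = 0.0526) and the chemokine genes Cxcl1 at -1.07 and Cxcl2 at -0.86. The list mean was 6.41 ± 0.08 in allogeneic and 6.96 ± 0.22 in syngeneic arrays (SD, n = 4 each), and camera called it (adjusted p = 2.68e-14, against an adjusted p = 0.146 with an estimated correlation). Of 32 genes of leukocyte adhesion and endothelial activation Cxcl5 fell, and 13 fell when adjusted over the list alone. Icam1, which encodes a ligand of leukocyte integrins, had a log2 change of -1.46 (limma adjusted p = 0.0827) and the iron-binding protein gene Lcn2 one of -1.05 (limma adjusted p = 0.0551). Camera called this list (adjusted p = 3.58e-08, against an adjusted p = 0.237 with an estimated correlation). With the epithelial covariate, with the endothelial one and without syngeneic arrays 3 and 4 its mean log2 change of -0.54 became -0.29, -0.31 and -0.28, and that of the NF-kB targets, also -0.54, became -0.37, -0.40 and -0.36. Both lists share Icam1, Cxcl1, Cxcl2 and further genes, so they are not independent. The endothelial list was highest on syngeneic arrays 3 and 4 (8.79 and 9.66), and syngeneic arrays 1 and 2 (8.08 and 7.76) lay within the allogeneic range.

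**Figure D3:**
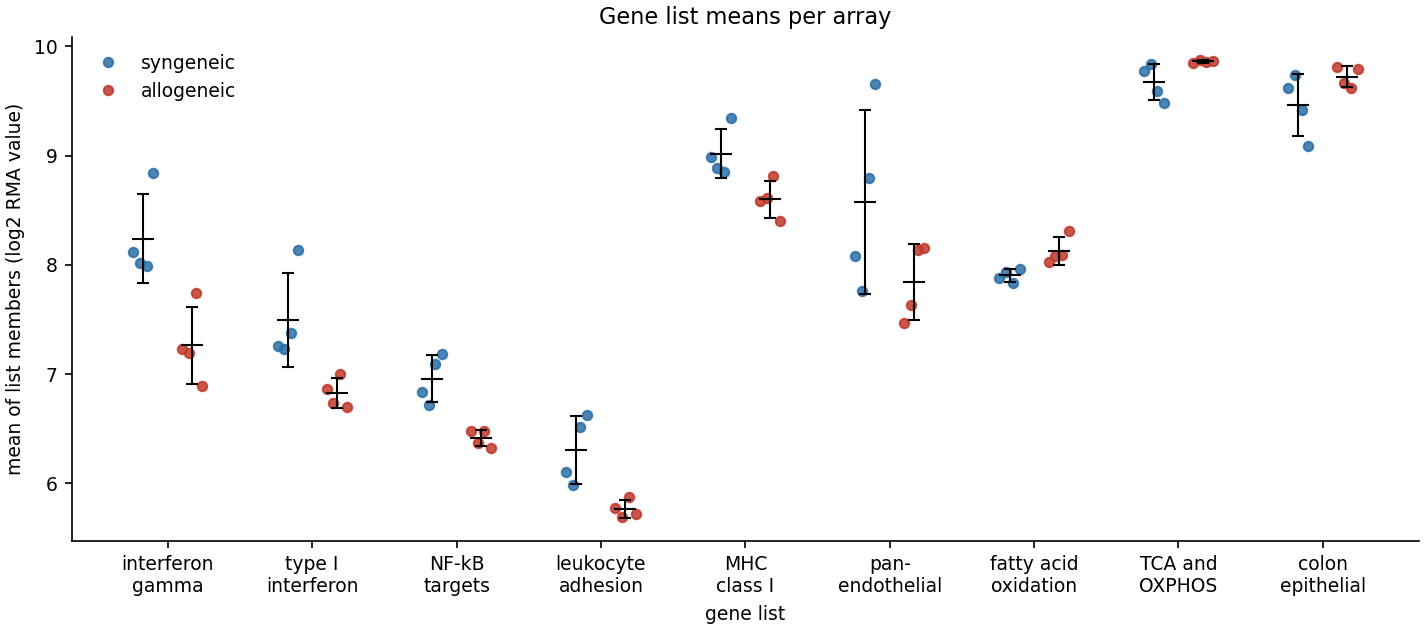
Mean log2 value of the members of 9 gene lists on each array. Points are arrays (4 per group), horizontal lines group means and bars ± 1 SD. The groups do not overlap for the interferon gamma list (7.26 against 8.24), while for the pan-endothelial list 2 of the 4 syngeneic arrays lie within the allogeneic range.

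All 25 members of the pan-endothelial list had a negative log2 change and none passed, over all genes or adjusted over the list alone. Eng, a coreceptor of the TGF-beta family, was at -1.43 ± 0.41, Plvap, the diaphragm protein of fenestrated endothelium, at -1.48 ± 0.50 and Robo4 at -1.08 ± 0.35 (SE, limma adjusted p = 0.158, 0.232 and 0.209). Pecam1 (-0.51 ± 0.33) and Cdh5 (-0.62 ± 0.37) did not pass (limma adjusted p = 0.557 and 0.514). Array means were 7.84 ± 0.35 in allogeneic and 8.57 ± 0.84 in syngeneic samples (SD, n = 4 each, two-sided exact permutation p = 0.171). The list passed camera (adjusted p = 1.06e-08), and lost the call otherwise (adjusted p = 0.487 with an estimated correlation). Without syngeneic arrays 3 and 4 the mean log2 change of the list was -0.08 in place of -0.73 (camera adjusted p = 0.514), an alternative chosen after the data were seen.

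Of 35 genes of basement membrane and extracellular matrix 30 had a negative log2 change, none passed over all genes and 2 fell when adjusted over the list alone. Timp1 (-0.73) and Timp3 (-1.17), inhibitors of matrix metalloproteases, had the smallest p-values. Camera called this list too (adjusted p = 1.15e-07, against an adjusted p = 0.487 with an estimated correlation). Angiogenesis and tip cell genes (35 measured) also passed (camera adjusted p = 0.000963, against an adjusted p = 0.534 with an estimated correlation), with the growth factor Vegfa at -0.44 and Flt4 at -0.86. The lists for venous and lymphatic genes, shear stress, tone and coagulation, and TGF-beta and BMP signalling passed camera with adjusted p = 0.0183, 0.0395 and 0.0342. All were lost otherwise (adjusted p = 0.585, 0.714 and 0.711 with an estimated correlation). Leaving out 1 array also ended these calls in 4, 5 and 3 of 8 fits (camera adjusted p up to 0.140, 0.606 and 0.539). In none of these lists did a gene pass over all genes. Without syngeneic arrays 3 and 4 all of these vascular lists lost their calls. Notch signalling and arterial genes did not pass (camera adjusted p = 0.452), but passed toward higher values with the epithelial covariate (0.26), with the endothelial one (0.28) and without both syngeneic arrays 3 and 4 (0.26), and toward lower values without syngeneic array 2 (-0.25).

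Of 38 measured genes of fatty acid uptake and oxidation 4 rose and none fell, 34 did not pass and 27 had a positive log2 change. Adjusted over the list alone, 12 rose. Hadha, the alpha subunit of the mitochondrial trifunctional protein, went from 8.95 ± 0.17 to 9.74 ± 0.10 (SD, n = 4 each, limma adjusted p = 0.0238), a 1.73-fold rise. Acaa2, a thiolase of the same pathway, rose 1.99-fold, and the acyl-CoA dehydrogenase genes Acads and Acadm rose 1.86-fold and 1.68-fold. The array means were 8.12 ± 0.13 against 7.90 ± 0.06 without overlap. The list passed camera (adjusted p = 2.75e-05, against an adjusted p = 0.237 with an estimated correlation). Of 45 genes of the TCA cycle and oxidative phosphorylation 39 had a positive log2 change, none passed over all genes and 5 rose when adjusted over the list alone, among them Suclg2 (1.08) and Ndufa1 (0.33). That list passed camera too (adjusted p = 5.02e-07, against an adjusted p = 0.487 with an estimated correlation), but not without syngeneic arrays 3 and 4 (camera adjusted p = 0.149). The oxidative stress list passed (camera adjusted p = 0.0119, against an adjusted p = 0.444 with an estimated correlation), but not without syngeneic arrays 3 and 4 (camera adjusted p = 0.0564) or with the epithelial covariate (0.0549), and its array means overlap. In it 6 of 28 genes rose when adjusted over the list alone, led by Nqo1, a quinone reductase (0.82, limma adjusted p = 0.0551). Glycolysis genes moved both ways (mean log2 change 0.01, camera adjusted p = 0.852). Adjusted over the list alone 2 of 25 rose and 2 fell, and fry passed the list in either direction (adjusted p = 0.000602). Galm was at 0.95 and Pfkp, a phosphofructokinase, at -0.62, neither past the threshold over all genes.

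The colon epithelial markers moved in the opposite direction to the endothelial ones. Their array means were 9.72 ± 0.10 in allogeneic and 9.46 ± 0.28 in syngeneic samples (SD, n = 4 each), with syngeneic array 4 lowest at 9.09 (two-sided exact permutation p = 0.114). Of 43 members 34 had a positive log2 change. Car2, a carbonic anhydrase, rose 2.69-fold (8.78 ± 0.46 to 10.2 ± 0.19) while Tac1 fell, and 5 rose when adjusted over the list alone, including the water channel gene Aqp8 (1.53) and the fatty acid binding protein gene Fabp2 (1.21). The list passed camera (adjusted p = 2.33e-05, against an adjusted p = 0.539 with an estimated correlation). Its mean log2 change was 0.26, and it lost the call without syngeneic arrays 3 and 4 (0.04, camera adjusted p = 0.606) and with the endothelial covariate (0.04, camera adjusted p = 0.807). The lists of fat oxidation and oxidative phosphorylation were higher in the same group as the epithelial list. With the epithelial list mean as a covariate the mean log2 change was 0.22 for fatty acid uptake and oxidation (0.22 without it) and 0.06 for the TCA cycle and oxidative phosphorylation (0.19 without it). The second list did not pass with it (camera adjusted p = 0.0955). Only 6 higher genes passed limma with this covariate, among them Cyp2c68, Cyp2c69, Nxpe2, Hao2 and Otc. Most of the called genes of fatty acid oxidation thus lost their call.

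Of the marker lists of other cell types 2 passed camera. Of 26 granulocyte and mast cell markers S100a8 fell, 4 fell and 1 rose when adjusted over the list alone, and most were dim. Hdc, the histamine-forming enzyme, was at -1.03 (limma adjusted p = 0.0526), S100a9 at -0.83 and the mast cell protease gene Cpa3 at -1.10. The list passed camera (adjusted p = 0.000469, against an adjusted p = 0.146 with an estimated correlation). It lost the call in 2 of the 25 settings in which it was tested (camera adjusted p up to 0.151). Smooth muscle and pericyte markers passed as well (camera adjusted p = 0.00106, against an adjusted p = 0.66 with an estimated correlation), with Pdgfrb at -0.53. Their mean log2 change of -0.28 became 0.00 with the epithelial covariate, 0.06 with the endothelial one and 0.08 without syngeneic arrays 3 and 4, none past the threshold. Markers of T and NK cells (camera adjusted p = 0.884), B and plasma cells (0.643), macrophages, monocytes and dendritic cells (0.151), platelets (0.0737), erythroid cells (0.97), fibroblasts (0.284), enteric glia and neurons (0.114) and adipocytes (0.151) did not pass. The macrophage list passed with the epithelial covariate (-0.15, camera adjusted p = 0.0486), without syngeneic arrays 3 and 4 (-0.17, camera adjusted p = 0.0359), without allogeneic array 3 (-0.22, camera adjusted p = 0.00136) and without syngeneic array 4 (-0.15, camera adjusted p = 0.0427), and its adjusted p was as high as 0.781 in other settings. Ptprc differed by 0.01 ± 0.39 and Itgam by -0.14 ± 0.20 (SE), neither past the test. Tested as array means, the granulocyte and mast cell list differed by -0.30 without overlap between the groups (two-sided exact permutation p = 0.0286, the smallest possible). Adjusted over 15 marker and RNA quality lists this p is 0.343, and with 4 against 4 arrays a single list cannot pass that adjustment.

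Among stress lists, hypoxia (camera adjusted p = 0.00222), apoptosis and cell death (0.00489), unfolded protein response (0.00106) and immediate early genes (2.33e-05) passed toward lower values. Their calls were lost with the correlation estimated (adjusted p = 0.237, 0.237, 0.444 and 0.479 with an estimated correlation). The hypoxia list lost its call in 2 of the 26 settings run, and its mean log2 change ranged from -0.26 to -0.09 over them. The immediate early list (mean log2 change -0.29) also lost its call without syngeneic arrays 3 and 4 (-0.09, camera adjusted p = 0.128), with the epithelial covariate (-0.08, 0.197) and with the endothelial one (-0.06, 0.342), and the apoptosis list with the epithelial covariate (-0.10, 0.0649). No member passed over all genes; adjusted over the list alone, 6, 2, 1 and 0 fell. P4ha2 (-0.60) and Hif1a (-0.51), Ripk3 (-0.65), a kinase of necroptosis, Atf4 (-0.34) and Zfp36 (-0.71) are examples. Among junction genes the tight junction gene Ocln rose 1.69-fold and F11r, which encodes the adhesion molecule JAM-A, fell (-0.53), and the list did not pass (camera adjusted p = 0.366). Cell cycle (0.0785), p53 and DNA damage (0.97), actin cytoskeleton (0.302), nucleotide synthesis (0.457), fatty acid and cholesterol synthesis (0.0541) and cytosolic ribosomal proteins (0.97) did not pass either, by camera adjusted p.

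In all, 21 of 39 lists passed camera with its preset correlation of 0.01, 4 higher and 17 lower, and 0 passed with the correlation estimated, where 8 had an unadjusted p below 0.05. By fry, which asks whether a list's own genes move, 2 lists passed in 1 direction and 19 in either. The 2 were NF-kB targets and granulocyte and mast cell markers (fry adjusted p = 0.0224 each). The interferon gamma (fry adjusted p = 0.0688), type I interferon (0.0762) and leukocyte adhesion (0.0688) lists did not pass in 1 direction.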

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

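The test of leukocyte markers, the tests of 11 and 6 genes outside the planned lists, the comparison of endothelial means without syngeneic arrays 3 and 4, and the covariate fits of gene counts were chosen after the results they concern were seen.

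An array stood far from the other 3 of its group in 12 of 142 groups of values tested, where chance gives such a gap in about 5% of groups. Of these 12 cases 8 concerned syngeneic array 4, and since they come from 1 array and from lists that share genes they are not independent. Syngeneic array 4 had the highest mean of its group for the type I interferon list (8.14, others 7.23 to 7.37), the interferon gamma list (8.84, others 7.99 to 8.12), the apoptosis list (7.94, others 7.72 to 7.76) and the adipocyte list (6.32, others 5.85 to 5.89). It had the lowest for the B and plasma cell list (5.17, others 5.41 to 5.45), Aadac (4.16, others 5.36 to 5.59), Clca4b (10.7, others 11.3 to 11.4) and Tac1 (6.37, others 6.64 to 6.68). Within the syngeneic group the T and NK cell list was highest on array 2 (4.48, others 4.40 to 4.41). In the allogeneic group, array 4 was high for the glia and neuron list (5.22, others 4.95 to 4.99) and for Hao2 (10.1, others 9.57 to 9.65), and array 3 was low for Fam83b (6.97, others 7.32 to 7.36).

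Probe sets without a gene symbol, which the comparison of genes left out, also held differences. In a limma fit of all 41345 probe sets, 7 of the 16010 without a symbol passed, 4 higher and 3 lower in the allogeneic group, with the largest log2 changes at 1.64 and -1.33.

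The real split gave the most genes, while it did not stand out in the number of lists. With 35 splits the smallest share possible is 1 of 35, so chance is not excluded for the gene counts. Splits that mix the donor types may also widen the spread within groups and so keep their counts low. Only 1 of the 35 splits of the arrays, the real one, gave as many as 79 higher genes, and likewise only 1 of 35 gave 25 lower genes, while the highest count of any other split was 0 in each direction. As many as 21 lists passed camera in 9 of the 35 splits, with up to 25 in another split. Lists thus pass with arbitrary groups of these arrays too, and a single list's camera p at the preset correlation is no measure of its link to donor type.

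The interferon gamma list was lower in the allogeneic group by 0.98 on the log2 scale (-0.98 ± 0.27, SE over arrays), and syngeneic arrays 3 and 4, which stood apart, do not account for it as a whole, since the difference without them was -0.80 ± 0.27. A lower share of endothelial RNA cannot be told apart from a change within the cells, because with the endothelial list mean as a covariate the difference was -0.71 ± 0.28, neither near 0 nor beyond -0.5 by more than its error; without syngeneic arrays 3 and 4 the endothelial means differed by -0.08, with a wide 95% interval from -0.85 to 0.70. Carried-over leukocyte RNA stays open as well, with the brighter macrophage markers at -0.0918 ± 0.173 and the brighter T and NK cell markers at 0.0127 ± 0.105. Granulocyte and mast cell markers, most of them dim, were lower by 0.30 without overlap between the groups (two-sided exact permutation p = 0.0286), although the sort excluded CD45 and CD11b. The leukocyte genes Ptprc, Cd3e and Lyz2 averaged 5.20, 4.93 and 6.70, levels that do not measure how much leukocyte RNA was present. A weaker response to interferon after allogeneic transplantation is the hypothesis the design offers, and it was not tested separately from these.

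The 79 genes that rose had a median log2 change of 1.18, against 0.26 for the mean of the epithelial list. For the 79 as a set this argues against a larger amount of epithelial RNA alone, while for single genes it is not settled. The 79 genes were selected for their difference on these same arrays, which holds up their median change. With the epithelial list mean as a covariate their median log2 change was 0.97 in place of 1.18, between 0.93 and 1.03 with each array left out, and 78 of the 79 were above 0.5 with it, against 77 without. Only 6 genes still passed, although the median standard error was 0.185 without and 0.181 with the covariate; the change was smaller and a degree of freedom was spent, and which of these ended the calls was not tested. The clock lists met the bounds set beforehand against a different hour of harvest. The evening list was at 0.11 (95% interval -0.14 to 0.36) and the morning list at 0.10 (-0.17 to 0.37). Members of the evening list moved both ways, with Dbp at 0.49 and Per1 at -0.45, neither past the threshold over all genes. Opposite shifts can cancel in a list mean, so a different hour stays open. A different part of the colon cannot be told apart, as the posterior Hox list differed by 0.25 (-0.02 to 0.52) and the anterior one by -0.06. A change in the state of the epithelial cells whose RNA was in the sorted samples, or of the endothelium, is an open and untested explanation tied to donor type. The sort selected CD31, and whether whole epithelial cells or only their RNA was carried over was not tested.

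Among the 25 genes that fell are Lrg1, Slpi and Zbtb16, and whether the 25 share a function was not tested. A list of 16 other measured epithelial antimicrobial and acute phase genes, chosen without those past the threshold, differed by -0.29 (95% interval -0.63 to 0.05, two-sided exact permutation p = 0.0857, 0.343 adjusted over 6 lists). It held Lcn2 and S100a9, whose lower values were known from other lists and did not pass over all genes (limma adjusted p = 0.0551 and 0.059). Of the 16 genes 10 were lower and 6 higher, with Nos2 at -1.73 and Ang4 at 1.74, so opposite changes can cancel in the list mean. The 11 genes of this list outside the planned lists differed by -0.25 (95% interval -0.65 to 0.15, two-sided exact permutation p = 0.171). A list of 14 glucocorticoid-responsive genes, Lcn2 among them, differed by -0.20 (95% interval -0.51 to 0.11, two-sided exact permutation p = 0.229, 0.457 adjusted), and its 6 genes outside the planned lists by -0.13 (-0.49 to 0.24). With 4 arrays per group neither a weaker acute phase nor a weaker glucocorticoid response can be told apart from no such difference.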

How the results depend on the processing

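The epithelial and endothelial covariates, the fit without syngeneic arrays 3 and 4 and the fit of all probe sets were chosen after the data were seen; the other settings were planned. The named genes Cyp2c68, Cyp2c69, Nxpe2, S100a8, Lrg1 and Tac1 passed in every setting in which they were tested, and no named gene of the 24 reversed. The other 18 each lost their call in some settings, from 1 of 25 for Hao2 to 15 of 24 for Sult1c2, whose log2 change ranged from 1.49 to 2.61; Stat2 lost it in 11 of 25, Cxcl10 in 11 of 24 and Aadac in 10 of 24.

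Against 79 higher and 25 lower genes, 136 and 54 passed among genes at or above the median probe set and 138 and 55 above the 75th percentile, where fewer genes were tested. An adjusted p below 0.10 gave 203 and 102, and an unadjusted p below 0.05 with a 1.5-fold change 628 and 445. Array weights gave 115 higher and 39 lower. Centring on brighter genes gave 69 and 38, so that 64.5% of calls were higher in place of 76.0%. With the epithelial covariate 6 and 4 genes and 13 lists passed, with the endothelial one 19 and 10 genes, without syngeneic arrays 3 and 4 26 and 12 genes and 13 lists, and with all probe sets in 1 fit 6 and 3 genes. By camera with the correlation estimated 0 lists passed, and 8 had an unadjusted p below 0.05. Beyond fewer genes or arrays, the cause was not tested.

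Leaving out 1 array gave 4 to 145 higher and 4 to 35 lower genes. The counts were 4 and 5 without allogeneic array 1, 15 and 4 without allogeneic 2, 32 and 13 without allogeneic 3, 13 and 8 without allogeneic 4, 26 and 5 without syngeneic 1, 145 and 35 without syngeneic 2, 4 and 4 without syngeneic 3, and 92 and 34 without syngeneic 4. Lists passing ranged from 19 to 24.

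With the replicate number as a block 40 higher and 28 lower genes and 23 lists passed. The numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.05, 0.05, -0.10 and 0.10.

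Some lists turned positive, in the order epithelial covariate, endothelial covariate and, where a value is given last, without syngeneic arrays 3 and 4. Their mean log2 changes were 0.264, 0.277 and 0.260 for Notch signalling and arterial, 0.0533, 0.0841 and 0.0421 for shear stress, tone and coagulation, 0.0522, 0.0889 and 0.0295 for TGF-beta and BMP signalling, and 0.135, 0.148 and 0.104 for junctions and permeability. The Notch list thereby passed camera toward higher values in all 3 (adjusted p = 0.00161, 9.22e-05 and 0.00181, up to 0.922 over all settings run). Junctions passed with the epithelial and the endothelial covariate (camera adjusted p = 0.0345 and 0.00437, up to 0.820) and not without syngeneic arrays 3 and 4 (0.0801). Without syngeneic array 2 the Notch list passed toward lower values (-0.25, camera adjusted p = 0.0465). Angiogenesis and tip cell stood at -0.00175, with camera's own direction up, and 0.0399. Smooth muscle and pericyte markers stood at 0.0644 with the endothelial covariate and 0.0759 without syngeneic arrays 3 and 4. The cause was not tested. Signal over background was not used here beyond the level of 4 Y-linked genes, so how far background limits dim genes is not known.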

Other observations

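The genes of the first paragraph were picked after their values were seen. Besides the genes with the largest changes, other genes passed in limma toward higher values, and whether they share a function was not tested. They included the cytochrome P450 genes Cyp2w1 (log2 change 1.11) and Cyp2f2 (1.01), the sulfotransferase gene Sult1a1 (1.33), the aldehyde dehydrogenase gene Aldh1a7 (1.22), the monoamine oxidase gene Maob (1.63) and Hpgd (1.26), which inactivates prostaglandins. Dpep1, a membrane dipeptidase, rose from 9.26 ± 0.37 to 10.8 ± 0.21 (SD, n = 4 each, limma adjusted p = 0.00979). Genes that passed toward lower values included the mucin gene Muc1 (-1.16), the matrix protease gene Mmp7 (-1.10), Acod1 (-0.93), which makes itaconate, and the antiviral deaminase gene Apobec3 (-0.86). A dimmer second probe set of Mmp7 showed -0.18, and a second one of Cyp2f2, nearly as bright as the first, showed 0.09.

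The 10 measured genes encoded by the mitochondrial genome averaged 11.9 ± 0.18 in allogeneic and 11.6 ± 0.11 in syngeneic arrays (SD, n = 4 each, two-sided exact permutation p = 0.0571, adjusted p = 0.343). Cell cycle genes, which did not pass over all arrays, were lower with the epithelial covariate (mean log2 change -0.19, camera adjusted p = 0.000979), with the endothelial covariate (-0.23, camera adjusted p = 1.9e-05) and without syngeneic arrays 3 and 4 (-0.23, camera adjusted p = 8.6e-05). Over all settings run, the cell cycle list's camera adjusted p lay between 1.9e-05 and 0.828, the latter without allogeneic array 4, where the mean change was 0.03. Of the planned settings, it also passed without allogeneic array 1 or 3, without syngeneic array 3 or 4, with quantile normalization, with filters on dim genes and at an adjusted p below 0.10. The 3 settings named first were added after the data were seen, and no explanation was tested.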
